A study of soil metagenome with 30 samples.

How the data were processed

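Soil samples from Barrow, Alaska, taken from an organic and a mineral layer, were incubated in the laboratory and their microbial DNA was hybridised to a GeoChip, a microarray of oligonucleotide probes for microbial genes that carry out known functions. Per the labels, there were 30 samples in 10 groups of 3 replicates: in each layer a control at day 0, samples with the temperature tag 8 °C at days 60 and 122, and samples with the tag −2 °C at days 34 and 122. Within the labels the tag and the free text disagree: samples tagged 8 °C are described there as kept near freezing, and those tagged −2 °C as kept at the temperature of the warmest month. The groups are therefore named here by their tag, and nothing is said about which of them was the warmer. Per the labels' protocols, DNA was obtained by freeze-grinding lysis, cleaned on a gel, quantified with PicoGreen and labelled by random priming. The dye is given as Cy3 in one place and as Cy-5 in another. The scanner, the extraction software and the filter behind the blank values are not given in the sources used here. Nothing in the labels says that the replicates came from separate soil cores, so each p-value measures the spread between these samples, which can be technical.

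The table used was the deposited raw table, which holds 1 intensity per probe and array on a linear scale for 78730 probes of 1137 gene families, with a blank where the authors gave no value. The second deposited table, called normalized by the authors, holds the natural log of the raw value plus 1, with a largest deviation of 5.09e-09 and no scaling between arrays. In 5 of its 30 columns, all from mineral samples tagged 8 °C, it holds values that the raw table gives under another sample's name. The names of the raw table were used throughout, and the other naming was run as an alternative. Because the natural-log table is not scaled between arrays, the normalized signal that the design called for was made here from the raw intensities: log2 of each intensity minus the median log2 intensity of that array over the 25926 probes detected on all 30 arrays. A blank was taken as not detected: it was missing in the tests of single probes, was left out of the means of log2 values, and added no signal (a value of 0) to the family and organism sums, the Shannon index and the Bray-Curtis distances. The number of arrays limits the precision of every value.

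Gene families, organisms and lineages were taken from the columns of the deposited table, with family names as written there. A probe was retained in a fit if it was detected in at least 2 of 3 replicates of at least 1 group of that fit. A family's value on an array was log2 of the summed scaled signal of its retained probes, so a family can be carried by its brightest probe. The probe that changed most is the 1 with the largest change of mean scaled signal in the family's own direction. Its part is given of the net change over all probes, so it can exceed the whole. Values without it are ratios of mean scaled signals, not limma estimates. Because of how it is chosen, leaving it out tends to shrink a change. Only families with signal on all arrays of the fit were tested. For tests of single probes, a probe had to be detected in at least 2 of 3 replicates of every group, and undetected values were missing. Comparisons within a layer used its 15 arrays with 1 mean per condition and a shared estimate of the spread. The layer comparison and the tests of differences between layers used all 30 arrays with 1 mean per group. Fold changes, standard errors (SE) and p-values came from limma 3.58.1 (moderated variances with an intensity trend) in R 4.3.3, with the Benjamini-Hochberg adjustment over families or probes and a threshold of 0.05. Tests were two-sided.

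The families named in the text followed a rule fixed, like the tests, the gene lists and most of the alternatives, before the data were examined. In each comparison of 2 groups, the families past the threshold with at least 3 retained probes and no overlap between the groups' values were ranked, and up to 8 with the highest and up to 8 with the lowest log2 fold change were named. For the layer comparison overlap was not examined. Instead, the sign of the difference between group means had to be the same in all 5 conditions. In the layer comparison and those at day 122, every measured member of a list of 38 genes of soil carbon, nitrogen, sulfur, phosphorus and stress functions was also followed, of which 36 were found. Of 31 gene lists, 22 had at least 3 measured families. Of the 265 names on them, 167 were found. Lists were tested with camera (limma) at a preset correlation of 0.01 and again with an estimated correlation, in the layer comparison and the day 122 comparisons, and up to 4 members with the smallest p were named per list. The lineage column sorted probes into bacteria (70730 probes), archaea (2178), fungi (3628), viruses (882) and other eukaryotes (915), whose summed signals were tested in the same way without the intensity trend, and 397 probes had no lineage.

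The number of detected probes and the Shannon index were compared by permutation tests with 100000 resamples. Differences in composition were tested by PERMANOVA (adonis2, vegan 2.7.1) on Bray-Curtis distances of the scaled signal with 99999 permutations, and displayed by principal coordinates. Figures were drawn with matplotlib 3.10.9. Before use, the fitting code was tested on simulated data in which a seeded set of families or probes was shifted by known amounts. In the simulated layer comparison, 86.6% of families shifted by 0.25, 97.0% shifted by 0.5 and 100% shifted by 1 (log2) were recovered. For tag 8 °C at day 122 against the control in the organic layer, the shares were 58.2%, 80.6% and 95.5%, and for the same comparison in the mineral layer 49.3%, 70.1% and 95.5%. Among called families, 5.03%, 6.59% and 0.694% in those 3 comparisons had not been shifted. The simulated noise was independent between families, and errors that the families of an array share were not simulated. The shares therefore need not hold for the real arrays. These shares are from a second random draw, made with another seed after the results had been seen; no setting was changed between the draws.

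The alternatives were another scaling between arrays (quantile, equal total), family values as shares of the total signal or as mean log2 over always-detected probes, no filter or a stricter filter on probes, no intensity trend, all 30 arrays in 1 fit, each layer with its own spread, the replicate number as a block, each replicate left out in turn, the 3 mineral samples whose titles end in another letter left out, and other distances for the composition. Added after the data were seen were the column names of the second table, unscaled values, a common signal floor, the number of detected probes as a covariate, sums over gene categories, subcategories and phyla with at least 50 probes, and the layer difference in the effect of tag 8 °C at day 122 against the control.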

Results

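The microbial genes of tundra soil were profiled in 30 samples, 15 from an organic and 15 from a mineral layer. Each layer had 5 conditions of 3 samples: a control at day 0, incubations tagged 8 °C sampled at days 60 and 122, and incubations tagged −2 °C sampled at days 34 and 122. The number of detected probes per array differed widely, from 29320 (organic, tag 8 °C, day 122, replicate 3) to 70347 (organic, tag 8 °C, day 60, replicate 3). In the organic layer it was 67587 ± 1297 (SD, n = 3) in the control, 67781 ± 2427 at tag 8 °C and day 60, and 42479 ± 11450 at tag 8 °C and day 122. Samples tagged −2 °C in that layer had 53771 ± 11894 probes at day 34 and 53918 ± 8284 at day 122. Mineral samples had 55185 ± 13500 probes in the control, with 39844 on replicate 3. They had 50787 ± 5760 and 51777 ± 6431 at tag 8 °C on days 60 and 122, and 61995 ± 1797 and 58998 ± 2800 at tag −2 °C on days 34 and 122. Arrays with fewer detected probes had a higher lowest deposited intensity, with r = −0.956 and rho = −0.939 in the organic layer and r = −0.887 and rho = −0.868 in the mineral layer (n = 15 arrays each). Permutation p was 1e-05 for both r and for the organic rho, the smallest that the resampling can give, and 6e-05 for the mineral rho. Without the 2 arrays farthest from the median the values of r were −0.918 and −0.796. Over the probes detected on all arrays, replicate 1 of the mineral samples at tag −2 °C and day 34 was 9.37-fold brighter than the geometric mean of the arrays. Scaled signals of samples in the same group had a median correlation of 0.976 across probes, against 0.967 for other conditions of the same layer and 0.877 for the other layer.

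**Figure D1:**
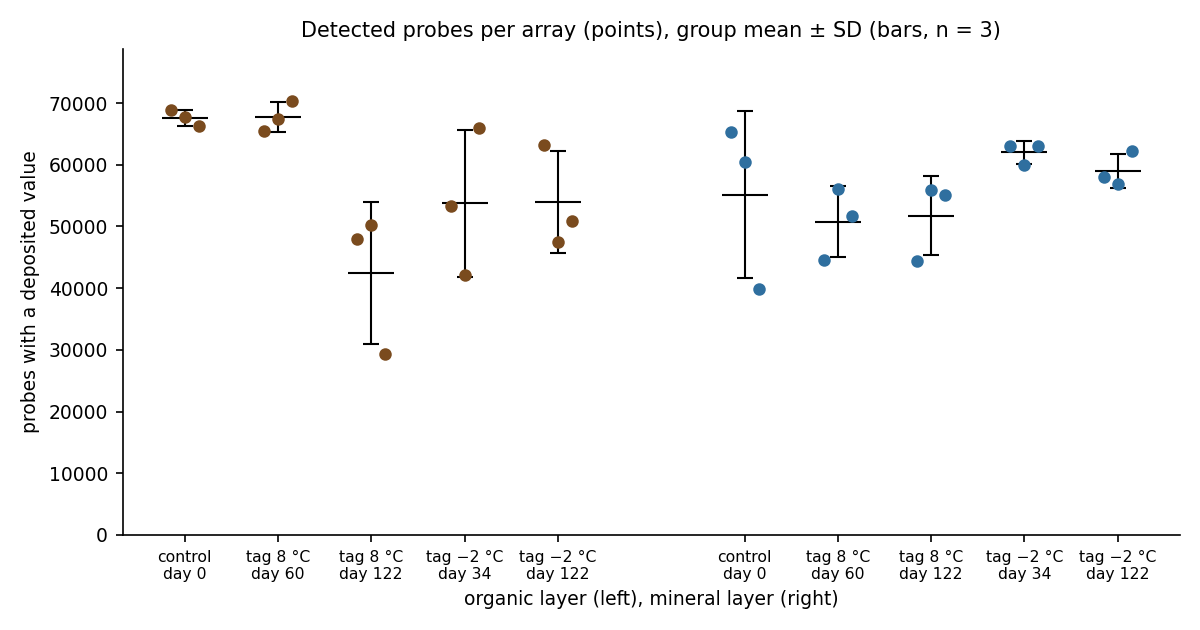
Number of probes with a deposited value on each array, by layer and condition, with 1 point per array and the mean ± SD of the 3 arrays of each condition. The organic samples tagged 8 °C at day 122 averaged 42479 probes, against 67587 in the organic control.

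Families with signal on all 30 arrays, at least 3 probes and the same sign of the mean difference in all 5 conditions were ranked. The largest excess in the organic layer was in nhaC, a family of sodium/proton antiporters, at 3.77-fold (log2 1.91 ± 0.09 SE, n = 15 samples per layer, adjusted p = 1.53e-14). The largest deficit among these families was in fosx, which encodes an enzyme of fosfomycin resistance, at 0.235-fold (log2 −2.09 ± 0.06, adjusted p = 3.82e-20). The family accD, singled out after its values were seen, was not tested because 1 mineral array had no signal for it. It stood at 14.11 to 15.66 (log2) on the organic and 9.41 to 10.59 on the other mineral arrays. Higher in the organic layer were also phlD, of diacetylphloroglucinol antibiotic synthesis (0.98 ± 0.06), the oomycete toxin family PcF_Oomycetes (0.97 ± 0.06) and mce3 (0.94 ± 0.08). The Legionella secretion gene icmQ (0.91 ± 0.13), c_type_cytochrome_6 (0.89 ± 0.05) and Ni_Fe_hydrogenase (0.87 ± 0.08) were higher too. Lower were PAPS_reductase of assimilatory sulfate reduction (−1.34 ± 0.09), the plant and green algal respiratory gene cox1_Viridiplantae (−1.29 ± 0.12) and the fungal iron regulator hapX (−1.27 ± 0.07). So were cdhC_methane (−1.15 ± 0.09), DNA_polymerase_type_I (−1.11 ± 0.07) and the quorum sensing regulator rsaL (−0.97 ± 0.09). For p48_hypoviridae, a protein of fungal hypoviruses (1.39 ± 0.09), and for GAPDH_Euglenozoa (−1.09 ± 0.08) the direction depended on the summary, with −0.56 and 0.12 as the mean log2 of probes detected on all arrays. Without the probe that changed most, p48_hypoviridae was −0.23, phlD −0.46, PcF_Oomycetes −0.69, mce3 −0.14 and cox1_Viridiplantae 0.12. Without its own such probe fosx was −0.06. The rest of these families shrank but kept their sign without such a probe. There nhaC was 1.00, Ni_Fe_hydrogenase 0.67, icmQ 0.50 and c_type_cytochrome_6 0.45. Of the lower ones rsaL was −0.87, PAPS_reductase −0.77, hapX −0.74, DNA_polymerase_type_I −0.62, GAPDH_Euglenozoa −0.47 and cdhC_methane −0.36. Each of these 16 families had the same sign in all 5 conditions. In limma, 538 of 813 families passed an adjusted p of 0.05, 221 higher and 317 lower in the organic layer. Of the net change over a family's probes, a single probe carried the larger part in 182 of the 221 and 233 of the 317. Without it, 59 of the higher and 69 of the lower families had the opposite sign or no change. As mean log2 of always-detected probes, 16 of 216 higher and 79 of 313 lower families had the opposite sign. Quantile normalization left 174 families (97 higher and 77 lower), and unscaled values, which carry the bright array and move the median family from −0.03 to −0.18, left 63.

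**Figure D2:**
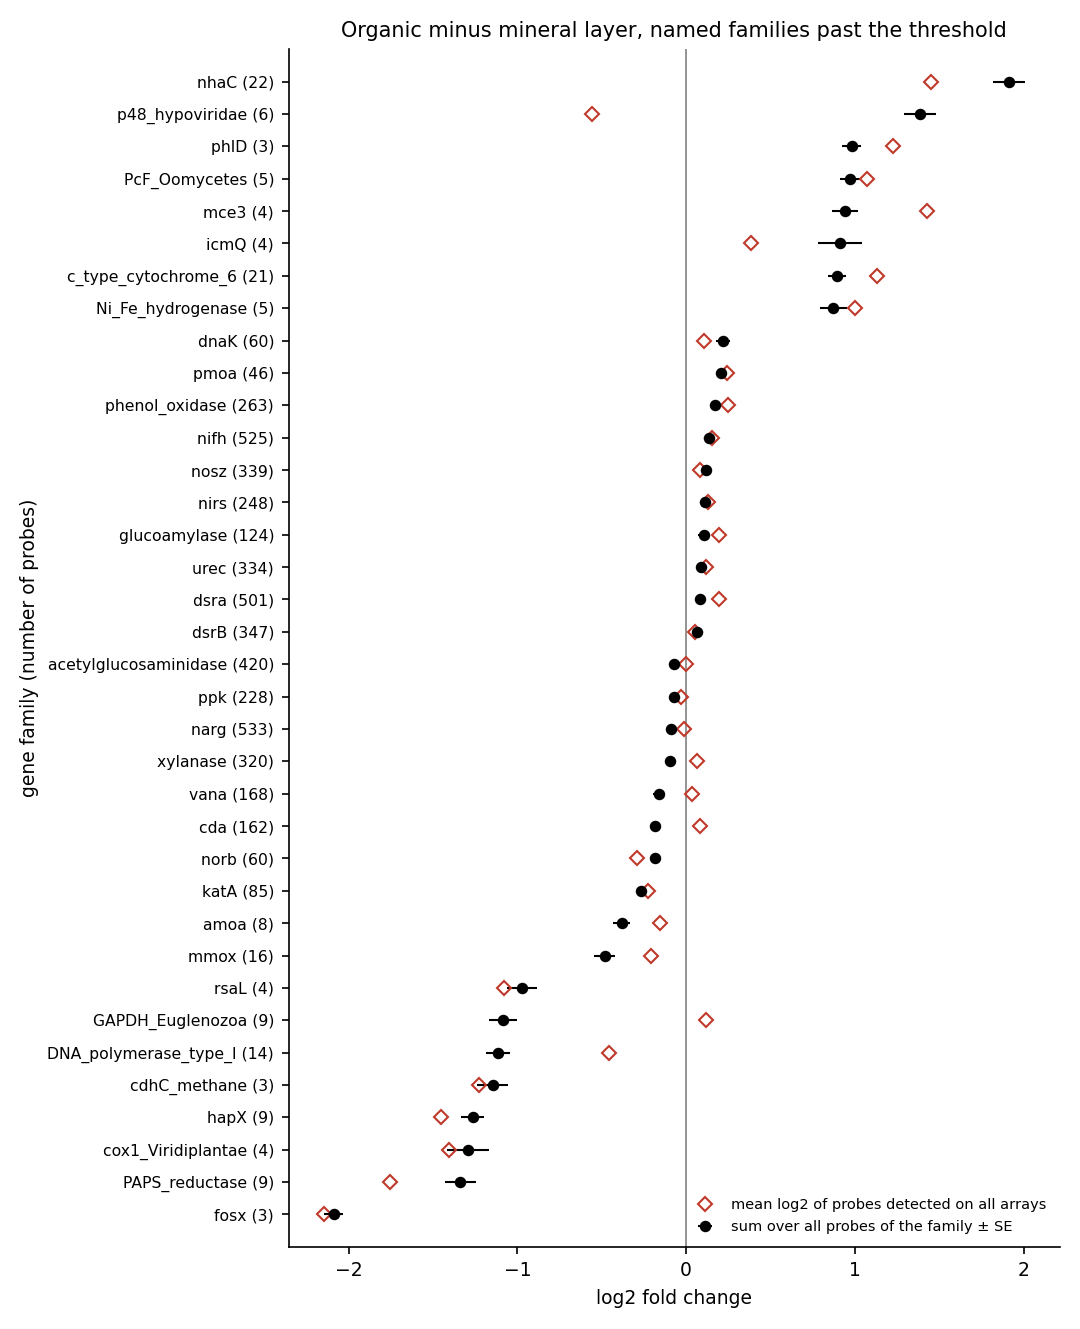
Log2 fold change, organic minus mineral layer, of 36 named families, as sums over probes (black dots, ± SE) and as mean log2 of the probes detected on all arrays (red open diamonds), with probe numbers in brackets. The sums run from −2.09 for fosx to 1.91 for nhaC, and the 2 summaries have opposite signs for p48_hypoviridae (1.39 and −0.56) and GAPDH_Euglenozoa (−1.09 and 0.12).

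Among the 36 measured genes of carbon, nitrogen, sulfur, phosphorus and stress functions followed by name, 10 were higher and 10 lower in the organic layer, and 20 passed when adjusted over the list alone. The methane and ammonia oxidation genes went both ways: pmoa, of the particulate methane monooxygenase, was higher (0.20 ± 0.02). Lower were mmox, of the soluble methane monooxygenase (−0.48 ± 0.06), and amoa, of ammonia monooxygenase (−0.38 ± 0.05). A single probe from Citreicella gave 98.1% of the mmox change, which was −0.02 without it, and a single archaeal probe gave 93.5% of that in amoa, which was −0.17 without it. Of the denitrification genes, the nitrite reductase gene nirs (0.11 ± 0.03) and the nitrous oxide reductase gene nosz (0.12 ± 0.02) were higher with scaled values but −0.04 and −0.03 with unscaled values. A single Robiginitalea probe carried the nosz change, which was 3.8e-05 without it. The genes norb (−0.18 ± 0.02) and narg (−0.09 ± 0.02), for nitric oxide and nitrate reduction, were lower. The nitrogenase gene nifh (0.13 ± 0.03), the urease gene urec (0.09 ± 0.02), glucoamylase (0.10 ± 0.03) and the dissimilatory sulfite reductase genes dsra (0.08 ± 0.02) and dsrB (0.07 ± 0.02) were higher, with unscaled values of −0.02, −0.06, −0.05, −0.07 and −0.09. The heat shock gene dnaK (0.22 ± 0.04) and phenol_oxidase of lignin degradation (0.17 ± 0.02) were higher, and the catalase gene katA (−0.27 ± 0.02) and the polyphosphate kinase gene ppk (−0.07 ± 0.02) were lower. The degradation genes cda (−0.18 ± 0.02), vana (−0.16 ± 0.03), xylanase (−0.10 ± 0.02) and acetylglucosaminidase (−0.07 ± 0.02) were lower as sums, but 0.08, 0.04, 0.06 and 0.00047 as mean log2 of always-detected probes. The methanogenesis marker mcra did not pass (−0.08 ± 0.09, adjusted p = 0.431), and except for narg the sign of all 20 was the same in the 5 conditions.

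Of the heat shock genes, 5 of 8 measured members were higher in the organic layer and 2 lower (median 0.15). They were led by the regulator ctsR (0.49 ± 0.04), the chaperonin genes groES (0.36 ± 0.03) and groEL (0.22 ± 0.04), and dnaK, and 7 passed when adjusted over the list alone. Both lower members turned as mean log2 of always-detected probes, grpE to 0.09 and hrcA to 0.0060, and the higher member clpC turned to −0.08 without scaling. Of the genes for oxygen stress and limitation, 2 of 14 were higher and 9 lower (median −0.08), among them katA, the catalase gene katE (−0.15 ± 0.02) and the peroxide regulator oxyR (−0.23 ± 0.03), and 11 passed when adjusted over the list alone. Of the 9 lower members 4 turned as the mean log2: the cytochrome bd gene cydB (−0.13 ± 0.02 as a sum) to 0.03, ahpF to 0.0073, narH to 0.08 and narJ to 0.06. Both higher members turned without scaling, ahpC to −0.03 and arcA to −0.05. Vanillin, lignin and terpene degradation had 4 of 5 members lower and 1 higher (5 over the list alone), including the vanillin dehydrogenase gene vdh (−0.30 ± 0.03) and limeh (−0.22 ± 0.04). Of these, lmo was 0.14 and vana 0.04 as the mean log2, and the higher cdh was −0.05 without scaling. Assimilatory nitrogen reduction had 3 of 5 lower and 1 higher (4 over the list alone), including nirb (−0.45 ± 0.04) and nasa (−0.20 ± 0.02), which were −0.0073 and −0.09 as the mean log2. The higher member narb was −0.05 without scaling. In the list for nutrient limitation 5 of 11 were higher and 3 lower (8 over the list alone), with the nitrogen regulators tnrA (0.93 ± 0.07) and glnR (0.54 ± 0.03) and the sugar transporter bglP (0.40 ± 0.03) higher and the phosphate-binding gene pstS lower (−0.32 ± 0.03). The higher members glnA and bglH were −0.12 and −0.01 without scaling. Methanogenesis had 3 of 9 lower and 1 higher (4 over the list alone), with Ftr at −0.44 ± 0.04 and fmdB_fwdB at 0.23 ± 0.04, and the lower member Mer_methane was 0.04 as the mean log2. As whole lists, 0 of 22 passed in camera, where heat shock and oxygen stress were the 2 with an unadjusted p under 0.05 (adjusted p = 0.370 for each, and adjusted p = 0.958 for each with an estimated correlation).

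Summed by organism, fungi (−0.05 ± 0.02), other eukaryotes (−0.05 ± 0.02) and viruses (−0.05 ± 0.02) were slightly lower in the organic layer in limma (adjusted p = 0.0319 each), while bacteria and archaea were not past the threshold. These 3 calls became 0 as shares of the total signal, after quantile normalization, and without a single array in 9 cases. In the mineral layer those were replicate 3 of tag 8 °C at day 122, replicates 2 and 3 of tag −2 °C at day 122, replicate 2 of tag −2 °C at day 34, and replicates 1 and 2 of the control. In the organic layer they were replicate 1 of tag 8 °C at day 122, of tag −2 °C at day 122 and of the control, and the count was 1 without replicate 2 of tag 8 °C at day 122 or replicate 3 of tag −2 °C at day 34. Of single probes 30296 of 42615 differed, 13180 higher and 17116 lower.

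Layer accounted for 45.2% of the variation in Bray-Curtis distance (permutational analysis of variance, permutation p = 1e-05, the smallest possible). It was 14.3% on detected or undetected probes alone (permutation p = 0.0031) and 21.5% on log values (permutation p = 2e-05). Mean distances were 0.189 between layers, 0.119 between conditions of a layer and 0.0970 within groups. The second principal coordinate followed the number of detected probes within each layer (organic r = −0.993, rho = −0.939; mineral r = −0.939, rho = −0.964; n = 15 each, permutation p = 1e-05, the smallest possible). Without the 2 farthest arrays r was −0.990 and −0.959. With the relations to the lowest intensity these were 4 relations, with adjusted p-values of 1e-05 for r and at most 6e-05 for rho.

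**Figure D3:**
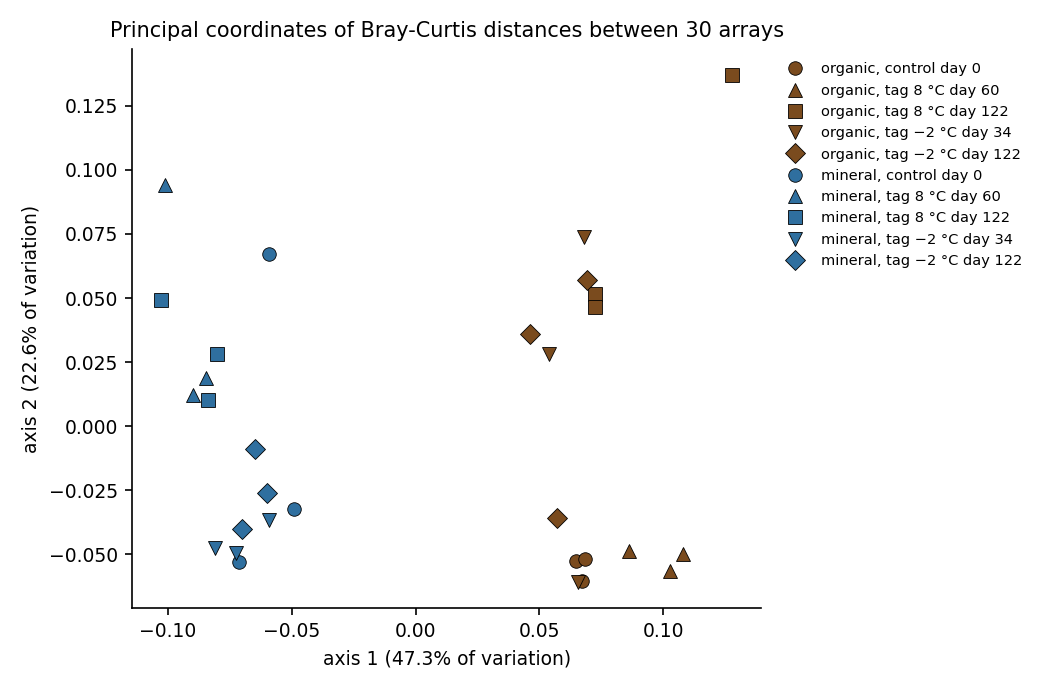
Principal coordinates of the 30 arrays from Bray-Curtis distances of scaled signal, with axis 1 at 47.3% and axis 2 at 22.6% of the variation and 1 point per array, coloured by layer (organic brown, mineral blue) with a marker shape for each condition. The layers separate along axis 1, and along axis 2 arrays with more detected probes tend to lie lower (r = −0.993 in the organic and −0.939 in the mineral layer).

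At day 122 of tag 8 °C in the organic layer, the sodium/proton antiporter family nhaC (1.07 ± 0.25, n = 3 samples per group), accD of fatty acid synthesis (0.95 ± 0.25) and mce3 (0.84 ± 0.17) were higher than in the control. After quantile normalization these 3 lost their calls, at 0.28, 0.27 and −0.06 (adjusted p = 0.295 to 0.862), and without scaling they were 0.27, 0.15 and 0.04 (adjusted p = 0.293 to 0.910). Taken as mean log2 of always-detected probes, nhaC was 0.50 (adjusted p = 0.0585), and accD and mce3 passed. Also higher were conidial_laccase (1.76 ± 0.56), a pigment oxidase of fungal spores, and pel_Cdeg (1.41 ± 0.46), for pectate lyases. After quantile normalization they were 0.56 (adjusted p = 0.290) and −0.13. The mercury transport gene merT (0.90 ± 0.21), mcra of the last step of methanogenesis (0.88 ± 0.21, adjusted p = 0.0153) and the sulfide oxidation gene sqr (0.85 ± 0.27) were higher too, but were −0.26, −0.14 and −0.20 after quantile normalization. Lower families were toxR, a virulence regulator (−1.33 ± 0.30), the methylamine methyltransferase gene mtmB (−1.13 ± 0.26), s1p1 (−1.12 ± 0.26) and the fungal zinc transporter zrt1 (−1.07 ± 0.33). Also lower were msmabcd of methanesulfonate oxidation (−1.01 ± 0.26), coat_Nepovirus (−0.99 ± 0.22), the streptomycin regulator strR (−0.97 ± 0.27) and ochratoxin_PKS (−0.89 ± 0.21). The lower families moved less as mean log2 of always-detected probes. There toxR (−0.26), zrt1 (−0.48), coat_Nepovirus (−0.15), strR (−0.40) and ochratoxin_PKS (−0.48) lost their calls (adjusted p = 0.0557 to 0.689), and mtmB (−0.89), s1p1 (−0.73) and msmabcd (−0.55) passed. In toxR 2.33 probes were detected on average, against 11.3 in the control. With the number of detected probes as a covariate zrt1 was 0.03, pel_Cdeg −0.32 and sqr −0.19. These 16 families were named among those whose values did not overlap between the 3 samples and the 3 controls. Over all tested families that held for 485 of 830, 58.4%, against 10% by chance for any 1 family. Families on the same arrays are not independent, so 10% is no yardstick for the share over families. In the organic comparisons of 2 conditions with 0 called families it ran from 2.53% to 41.7%, the highest at tag 8 °C and day 60 against the control. Of the 36 followed genes, 8 were higher and 0 lower, and 8 passed when adjusted over the list alone. Besides mcra they were phytase (0.43 ± 0.10), amoa (0.40 ± 0.08), vana (0.23 ± 0.06) and nosz (0.15 ± 0.04), each of them negative after quantile normalization (−0.33 to −0.72) and without scaling (−0.37 to −0.65). The amylase gene amyA (0.13 ± 0.02, adjusted p = 0.00607), rubisco (0.11 ± 0.03) and the carbon monoxide dehydrogenase gene codh (0.09 ± 0.03) completed them. These last 3 were negative after quantile normalization (−0.70, −0.69 and −0.74), without scaling (−0.68, −0.69 and −0.71) and at an equal total (−0.01, −0.03 and −0.05). Most of these rises rested on 1 probe each. Without it, mcra was −0.16, conidial_laccase −0.32, pel_Cdeg −0.45, mce3 −0.11, amoa −0.17, vana −0.11, merT −0.02 and sqr −0.0029, phytase was 0.01, nosz 0.0098 and nhaC 0.37, and in accD 1 probe gave 103% of the change. In mcra, 15 probes were higher and 68 lower.

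In limma, 228 of 830 families passed in that comparison, 146 higher and 82 lower, with a median family change of 0.00. The median moved to −0.85 with quantile normalization, −0.80 without scaling and −0.14 at an equal total or as shares, so directions are relative to the brightness of probes detected on every array. The counts were 723 (0 higher and 723 lower) with quantile normalization, 722 (3 and 719) without scaling and 297 (64 and 233) at an equal total. They were 293 (63 and 230) as shares and 270 (230 and 40) with a common signal floor. Of the called families, 132 of the 146 higher and 78 of the 82 lower had fewer probes detected at day 122 than in the control. The arrays as a whole also had fewer (42479 against 67587 on average). The share over all 830 families was not counted, so this is no trait of the called ones. With the number of detected probes as a covariate 3 families passed. The median change of the 228 families shrank from 0.37 to 0.12 while their median SE stayed near 0.0953 (0.0910), and 206 kept their direction. The count was 49 without replicate 3 of the incubated samples, and 9, 77 and 41 without replicates 1, 2 and 3 of the control. By organism group, bacteria (0.14 ± 0.04, adjusted p = 0.00271), archaea (0.18 ± 0.05, adjusted p = 0.00305) and fungi (0.19 ± 0.05, adjusted p = 0.00271) were higher with the default scaling, but all 5 groups were lower after quantile normalization and 1 was lower as a share.

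**Figure D4:**
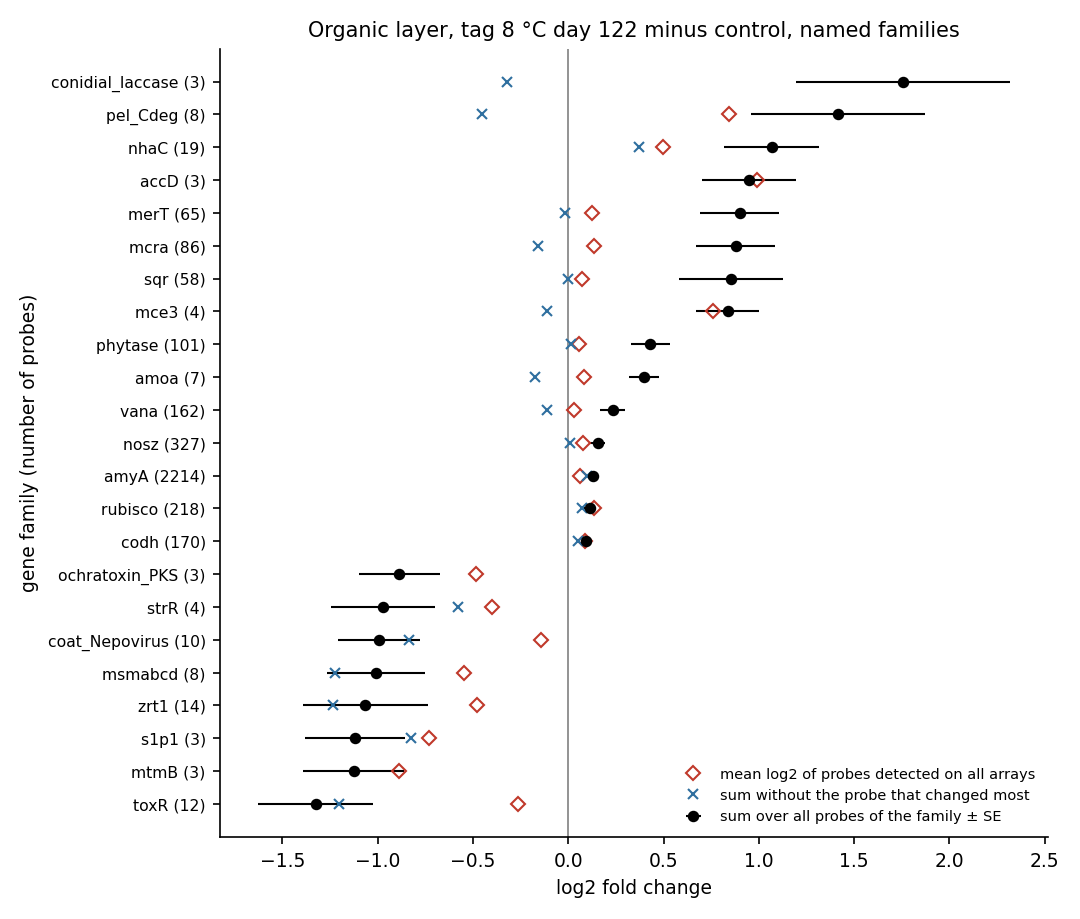
Log2 fold change of 23 named families in the organic layer, tag 8 °C at day 122 minus control: sums over probes (black dots, ± SE), mean log2 of the probes detected on all arrays (red diamonds) and sums without the probe that changed most (blue crosses), with probe numbers in brackets. For mcra the 3 values are 0.88 ± 0.21, 0.14 and −0.16 (and −0.14 as a sum after quantile normalization, not drawn), and for toxR the first 2 are −1.33 ± 0.30 and −0.26.

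In the list for nutrient limitation 6 of 11 members were higher and 1 lower (7 when adjusted over the list alone, median 0.13). Among them were tnrA (0.64 ± 0.14), the phosphate transporter gene pstA (0.25 ± 0.06) and bglP (0.25 ± 0.06), negative after quantile normalization (−0.23, −0.64 and −0.58) and without scaling (−0.16, −0.55 and −0.55). The glutamine synthetase gene glnA (0.09 ± 0.02) was negative with those settings (−0.73 and −0.71) and at an equal total (−0.05). The other higher members, phoA and pstB, were −0.54 and −0.61 after quantile normalization and −0.55 and −0.51 without scaling. Heat shock had 3 of 8 higher (5 over the list alone), namely groES (0.32 ± 0.06), clpC (0.27 ± 0.06) and groEL (0.26 ± 0.07), at −0.45, −0.61 and −0.52 after quantile normalization and −0.48, −0.53 and −0.54 without scaling. In sulfur oxidation 4 of 7 were higher (6 over the list alone), sqr among them, with soxB at 0.19 ± 0.06 and soxY at 0.17 ± 0.04. These 2 were −0.78 and −0.71 after quantile normalization and −0.61 and −0.63 without scaling. The fourth, fccab, was −0.69 and −0.68 with those settings and −0.02 at an equal total. Methanogenesis went both ways: of 9 measured, mcra, hdrB (0.35 ± 0.11) and fmdB_fwdB (0.30 ± 0.09) were higher and mtmB lower (4 over the list alone). The value of hdrB was −0.68 after quantile normalization and −0.45 without scaling, and that of fmdB_fwdB −0.44 and −0.51. In hemicellulose degradation mannanase (0.54 ± 0.14) and ara (0.31 ± 0.09) of 4 members were higher (2 over the list alone), at −0.41 and −0.61 after quantile normalization and −0.27 and −0.50 without scaling. As whole lists, 0 of 22 passed in camera, with nutrient limitation alone at an unadjusted p under 0.05 (adjusted p = 0.254, and adjusted p = 0.684 with an estimated correlation).

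From day 60 to day 122 at tag 8 °C in the organic layer, pel_Cdeg (1.72 ± 0.46), merT (0.99 ± 0.21), the CRISPR gene cmr6 (0.91 ± 0.20) and sqr (0.91 ± 0.27) were higher at the later time, all 4 below 0 after quantile normalization (−0.0025, −0.23, −0.32 and −0.18). So were mcra (0.89 ± 0.21), b_lactamase (0.88 ± 0.17), tannase_Cdeg (0.77 ± 0.19) and camdcab of camphor degradation (0.76 ± 0.18), at −0.16, −0.12, −0.47 and −0.47 after quantile normalization. Without the probe that changed most, pel_Cdeg was −0.28, merT −0.06, cmr6 −0.04, sqr −0.0050, mcra −0.24 and b_lactamase −0.04, and tannase_Cdeg was 0.08. Lower were s1p1 (−1.38 ± 0.26), mtmB (−1.36 ± 0.26), toxR (−1.31 ± 0.30), MT2 (−0.85 ± 0.27) and suc_CoA_red_DiC4HB (−0.83 ± 0.19). Their values as mean log2 of always-detected probes were −0.69 for s1p1, −1.19 for mtmB, −0.18 for toxR, −0.32 for MT2 and −0.47 for suc_CoA_red_DiC4HB. With the number of detected probes as a covariate MT2 was 0.12, pel_Cdeg −0.03 and sqr −0.14. Also lower as sums were coat_Nepovirus (−1.15 ± 0.22), strR (−1.03 ± 0.27) and 5f1_ppn (−0.89 ± 0.16), which were 0.12, 0.09 and 0.20 as mean log2 of always-detected probes. In limma 148 of 830 families passed, 100 higher and 48 lower (n = 3 per group), and 95 of the 100 and all 48 had fewer probes detected at day 122. Whole arrays had fewer too (42479 against 67781 on average), and the share over all 830 families was not counted. The median family moved to −0.86 with quantile normalization (734 families, 0 higher), to −0.63 without scaling (591 families) and to −0.16 at an equal total (354 families, 59 higher and 295 lower). With the number of detected probes as a covariate, or with families as mean log2 of always-detected probes, 0 families passed in limma (156 and 190 at an unadjusted p under 0.05). Leaving out replicate 3 of day 122 gave 80 families, and leaving out replicate 2 or 3 of day 60 gave 55 each. At day 60 itself, 0 of 830 families differed from the control in limma, with 76 at an unadjusted p under 0.05.

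At day 122 in the organic layer, mtbC_mttC, for corrinoid proteins of methylamine use (0.47 ± 0.09), replicase_Carmovirus (0.44 ± 0.08) and the copper efflux gene cusC (0.40 ± 0.08) were higher at tag 8 °C than at tag −2 °C. After quantile normalization, which moved the median family to −0.45, these 3 were −0.05, −0.0036 and −0.05. The chaperonin gene groES (0.36 ± 0.06) and rndA (0.14 ± 0.02) were higher too, but were −0.05 and −0.31 after quantile normalization and −0.02 and −0.24 without scaling. Lower was hrpP, a type III secretion gene (−0.99 ± 0.16). At an equal total hrpP passed (adjusted p = 0.0329) and the 5 higher families did not (adjusted p = 0.0869 to 0.236), and after quantile normalization hrpP did not (adjusted p = 0.199). Taken as mean log2 of always-detected probes, all 6 passed except groES and rndA (adjusted p = 0.0774 and 0.0635). An Aspergillus niger probe gave 92.6% of the groES change. In limma 7 of 830 families passed, 6 higher and 1 lower (194 at an unadjusted p under 0.05), among them the 2-probe family tsh, named after its values were seen (0.53 ± 0.08). The number was 23 without replicate 1 of tag 8 °C, 3 without its replicate 2 and 4 without replicate 1 of tag −2 °C. Of single probes 2430 of 46068 differed, 1613 higher and 817 lower, but 6 after quantile normalization. The number was 1535, 266 and 364 without replicates 1, 2 and 3 of tag 8 °C, and 497 and 3851 without replicates 1 and 3 of tag −2 °C. The followed genes lay between −0.26 and 0.30, with mcra highest (0.30 ± 0.21, adjusted p = 0.391), and 0 of 36 passed in limma. Of the 22 lists 0 passed in limma's camera and 1 had an unadjusted p under 0.05, nutrient limitation (median 0.14, adjusted p = 0.184, 4 over the list alone).

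Incubation tagged −2 °C gave 0 called families against the control in the organic layer. At day 122 mcra stood at 0.58 ± 0.21 (adjusted p = 0.444) and phytase at 0.34 ± 0.10, where 0 of 36 followed genes, 0 of 22 lists and 0 of 830 families passed in limma or camera. In families 91 had an unadjusted p under 0.05, and 2 were past the threshold without replicate 1 of day 122. At day 34 the number was 0, with 62 unadjusted, and 36 without replicate 3 of day 34. Between days 34 and 122 it was 0, with 12 unadjusted, and 1 without replicate 2 of day 34.

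In the mineral layer, at tag 8 °C and day 60, phospholipase_A2_fungi, for fungal enzymes that cleave phospholipids, was lower (−0.44 ± 0.07, adjusted p = 0.00825, n = 3 per group). It did not pass after quantile normalization (−0.53, adjusted p = 0.997) or as mean log2 of always-detected probes (−0.22, adjusted p = 0.167), but did at an equal total (adjusted p = 0.0390). Without the probe that changed most it was −0.22. The single-probe family shdA, named after its values were seen, was lower too (−0.74 ± 0.13, adjusted p = 0.0264). These were the 2 of 883 families that passed in limma, with 135 at an unadjusted p under 0.05. At day 122, mcra stood at 0.32 ± 0.16 (adjusted p = 0.391) and phytase at 0.22 ± 0.10, and 0 of 883 families passed, with 121 unadjusted. Without the 3 mineral samples whose titles end in another letter 0 families passed at day 60 (112 unadjusted). Without mineral control replicate 3, the array with 39844 probes, the counts were 9 at day 60 and 10 at day 122. At day 60 they were also 8 and 1 without replicates 1 and 2 of the incubation, and 1 and 0 without replicates 1 and 2 of the control. At tag −2 °C the followed genes lay between −0.21 and 0.12 at day 122. In limma 0 families passed at day 122 (1 unadjusted) and 0 at day 34 (28 unadjusted, and 1 called without replicate 2). Between the times 0 passed in limma at tag 8 °C (20 unadjusted) and 0 at tag −2 °C (5 unadjusted, and 1 called without replicate 2 of day 34).

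Between the tags at day 122 in the mineral layer, the nickel and cobalt efflux gene rcnA (−0.44 ± 0.08, adjusted p = 0.0400) and coat_Necrovirus (−0.58 ± 0.12, adjusted p = 0.0442) were lower at tag 8 °C than at tag −2 °C. Neither passed after quantile normalization (adjusted p = 0.513 and 0.416), and both passed at an equal total (0.0243 and 0.0481). The mean log2 of always-detected probes was −0.19 for rcnA (adjusted p = 0.0451) and −0.32 for coat_Necrovirus (adjusted p = 0.0737), and without scaling coat_Necrovirus did not pass (adjusted p = 0.974). Without the probe that changed most they were −0.31 and −0.17. Both were named among the families whose values did not overlap between 3 and 3 samples. Over all tested families that held for 264 of 883, 29.9%, against 10% by chance for any 1 family, which is no yardstick for families on the same arrays. In the mineral comparisons of 2 conditions with 0 called families it ran from 3.85% to 20.6%. The followed gene mcra stood at 0.53 ± 0.16 and mrtH, of a methyl-coenzyme M reductase, at −0.23 ± 0.07 (adjusted p = 0.124 both), and 0 of 36 passed in limma. In all 4 of 883 families passed, 1 higher and 3 lower, with 149 at an unadjusted p under 0.05. The other 2, named after their values were seen, were the single-probe families hrpY2 (1.26 ± 0.25) and sopE (−0.97 ± 0.18). The number was 1 without replicate 1 of tag 8 °C. It was 0 without its replicate 2 or 3, without replicate 1 or 2 of tag −2 °C, and without the 3 samples whose titles end in another letter (101 unadjusted). Methanogenesis had a median of −0.18 (adjusted p = 0.256 in limma's camera, 4 of its members past when adjusted over the list alone), and 0 of 22 lists passed, with 3 at an unadjusted p under 0.05. Of single probes 7137 of 49140 differed, 5600 higher and 1537 lower. The number was 178 after quantile normalization, which moved the median family to −0.25, and 2227 (1409 higher and 818 lower) among probes detected on all 15 arrays. Without replicate 2 or 3 of tag 8 °C the number was 1859 or 2697, and without replicate 1 or 2 of tag −2 °C it was 3335 or 2049.

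**Figure D5:**
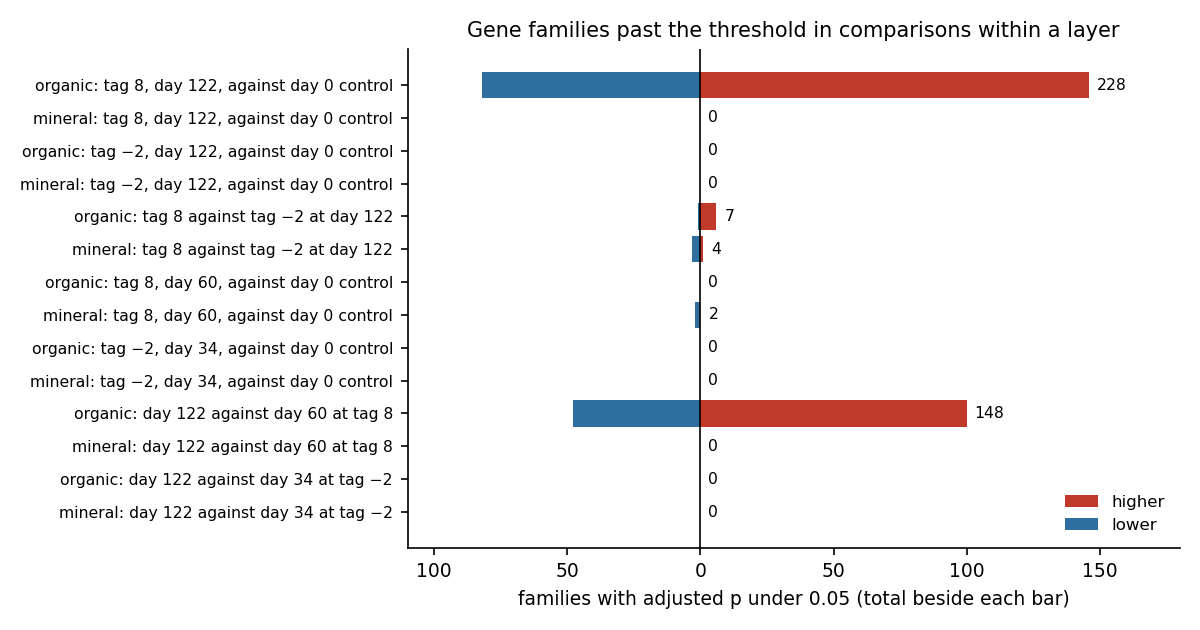
Number of families past an adjusted p of 0.05 in limma in each comparison between conditions, higher and lower shown separately, for the organic (830 tested) and mineral (883 tested) layers. Calls concentrate in the organic comparisons of tag 8 °C at day 122 with the control (146 higher and 82 lower) and with day 60 (100 and 48).

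Over all 5 conditions, 103 of 830 families and 3843 of 46068 probes varied in the organic layer, and 16 of 883 families and 8558 of 49140 probes in the mineral layer. The organic family count was 0 without tag 8 °C day 122 replicate 2 and 26 without its replicate 3. It was 5, 2 and 2 without replicates 1, 2 and 3 of tag 8 °C day 60, 2 without any of the 3 controls, 165 without tag −2 °C day 122 replicate 1, and 159 and 197 without replicates 2 and 3 of tag −2 °C day 34. Left out in the same order, these samples gave 266, 1662, 995, 66, 82, 333, 321, 337, 10840, 7230 and 12899 organic probes, and the number was 1172 without tag 8 °C day 122 replicate 1. The mineral family count was 8, 2 and 6 without replicates 1, 2 and 3 of tag 8 °C day 122, and 31 and 2 without replicates 1 and 2 of day 60. It was 9, 7 and 10 without replicates 1, 2 and 3 of tag −2 °C day 122, 5 without tag −2 °C day 34 replicate 3, and 10 and 39 without control replicates 2 and 3. It was 0 without the 3 samples whose titles end in another letter (99 at an unadjusted p under 0.05 in limma). Mineral probes numbered 5652 without tag 8 °C day 122 replicate 2.

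The number of detected probes differed among organic conditions (F = 4.94, permutation p = 0.0188) but not past the threshold among mineral ones (F = 1.26, permutation p = 0.341), nor between the layers (difference 1359 probes, permutation p = 0.696). The Shannon index, which rises with the number of detected probes and with the evenness of their signal, was 9.91 ± 0.0226 (SD, n = 3) in the organic control and 9.47 ± 0.256 at tag 8 °C and day 122. Evenness itself was 0.891 in both. It differed among organic conditions (F = 4.27, permutation p = 0.0231), not past the threshold among mineral ones (F = 0.366, permutation p = 0.858) or between layers (difference 0.00302, permutation p = 0.960). Leaving out the samples with replicate number 1, 2 or 3 ended the organic difference in detected probes (permutation p = 0.152, 0.0609 and 0.0907), and leaving out those with number 1 or 3 that in the Shannon index (permutation p = 0.198 and 0.0821).

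Condition accounted for 52.3% of the variation in composition within the organic layer (permutational analysis of variance, permutation p = 0.00558) and 42.6% within the mineral layer (permutation p = 0.0197). The first was lost without the samples numbered 1 (permutation p = 0.0561). The second was lost without those numbered 2 (permutation p = 0.363), without the 3 samples whose titles end in another letter (permutation p = 0.0825), on detected or undetected probes alone (permutation p = 0.251) and on log values (permutation p = 0.234). Organic samples at tag 8 °C and day 122 lay at a mean distance of 0.157 from the control, against 0.0409 among the controls and 0.112 among themselves.

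The layers differed in how tag 8 °C compared with tag −2 °C at day 122 in 19 of 813 families, 14 with a higher and 5 with a lower difference in the organic layer (limma, 145 at an unadjusted p under 0.05). The chaperonin family groES stood at 0.36 in the organic and −0.12 in the mineral layer, a difference of 0.48 ± 0.11 (adjusted p = 0.0155). The copper efflux gene cusC stood at 0.40 and −0.11, a difference of 0.50 ± 0.12 (adjusted p = 0.0321). Both differences were above 0 with every scaling tried, at 0.24 and 0.30 after quantile normalization, where the organic values were −0.05 each. Neither passed at an equal total, as a share, after quantile normalization or without scaling (adjusted p = 0.0665 to 1.00). That count was 9, 4 and 10 without replicates 1, 2 and 3 of the mineral samples at tag 8 °C, and 12 and 2 without replicates 1 and 2 of those at tag −2 °C. It was 7 without replicate 3 of the organic samples at tag 8 °C, and 6 without replicate 1 of those at tag −2 °C. It was 0 in limma after quantile normalization, which moved the median difference to −0.22 (10 at an unadjusted p under 0.05), and 40 with the column names of the second table.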

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

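Chosen only after the results were seen were the layer difference in the effect of tag 8 °C at day 122 against the control, the tests of summing over incompletely detected probes, of missing dim values and of an intensity-dependent shift among the probes detected on all 15 arrays, the unscaled values, the covariate, and the column names and column order of the second table.

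The difference between tag 8 °C and tag −2 °C at day 122 was not the same in both layers for 19 of 813 families (limma, interaction term, n = 3 per group). The coat protein family coat_Necrovirus differed by 0.68 ± 0.18 (0.10 in the organic and −0.58 in the mineral layer), the copper efflux gene cusC by 0.50 ± 0.12 and the chaperonin gene groES by 0.48 ± 0.11. The type III secretion gene hrpP differed by −0.74 ± 0.20 (−0.99 in the organic and −0.25 in the mineral layer). Adjusted p-values of these 4 ran from 0.0155 to 0.0435 in limma, and the signs of these differences were the same with every scaling tried. None of the 4 passed at an equal total (adjusted p = 0.0693 to 0.146), as a share (0.0665 to 0.145), after quantile normalization (0.903) or without scaling (1.00). As mean log2 of always-detected probes cusC alone passed (adjusted p = 0.0328, against 0.118 to 0.252). Of 100 random splits of the samples 2 gave as many families, the real one included, a share under 0.05. Another split gave 48, which points to a structure of the samples, so that share alone does not exclude chance. The count was 9, 4 and 10 without mineral replicates 1, 2 and 3 at tag 8 °C, 12 and 2 without mineral replicates 1 and 2 at tag −2 °C, 7 without organic replicate 3 at tag 8 °C and 6 without organic replicate 1 at tag −2 °C.

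The change from the control to tag 8 °C at day 122 was not the same in both layers for 43 of 813 families (limma, interaction term), 22 with a higher and 21 with a lower value in the organic layer. The antiporter family nhaC differed by 1.20 ± 0.30, with 1.07 in the organic and −0.13 in the mineral layer. The nitrous oxide reductase gene nosz differed by 0.25 ± 0.07, but by −0.56 after quantile normalization and −0.45 without scaling. Lower differences were those of the virulence regulator toxR (−1.51 ± 0.36), the fungal zinc transporter zrt1 (−1.27 ± 0.36), the streptomycin regulator strR (−1.15 ± 0.32) and ochratoxin_PKS (−0.98 ± 0.26). As mean log2 of always-detected probes none of these 6 passed (adjusted p = 0.0520 to 0.974): nhaC was 0.73, nosz 0.10, toxR −0.01, zrt1 −0.27, strR −0.58 and ochratoxin_PKS −0.51. None passed after quantile normalization (adjusted p = 0.0572 to 0.211) or without scaling (0.645 to 0.651), and all but nosz did at an equal total (adjusted p = 0.0170 to 0.0313, against 0.145) and as shares (0.0171 to 0.0306, against 0.140). Of 100 random splits 4 gave as many families, the real one included, and another split gave 149, which points to a structure of the samples. The share is under 0.05, but the comparison was chosen after the results were seen, so chance is not excluded. The count was 26, 3 and 14 without mineral replicates 1, 2 and 3 at tag 8 °C, and 3 and 20 without mineral control replicates 2 and 3. It was 96, 69 and 2 without organic replicates 1, 2 and 3 at tag 8 °C, and 2, 3 and 2 without organic control replicates 1, 2 and 3.

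In the organic layer 228 of 830 families, among them mcra, toxR and nhaC, differed between tag 8 °C at day 122 and the control (limma, n = 3 per group), whose arrays had 42479 and 67587 detected probes on average. Leaving out replicate 3 of day 122, the array with the fewest probes, kept 0.764 of their median change. Resampling the families gave 0.713 to 0.825, a range that does not measure the spread between samples. The families were called with that array included, so this shows only that it did not give the whole of their median change. As mean log2 of always-detected probes the median change was 0.385 of that of the sums (0.328 to 0.449, again by resampling the families). It shrank in both directions, from 0.29 to 0.12 in the higher and from −0.45 to −0.19 in the lower families. An undetected probe adds no signal, so summing over such probes may account for part of the falls. Fewer detected probes work against a rise, and 132 of the 146 higher families had fewer at day 122. The 2 summaries also weight bright probes differently, so their ratio cannot tell how much is due to undetected probes. The slope on detected probes within the 9 arrays of the other 3 organic conditions gave a share of 0.704. It was 0.472 to 0.992 with each of those arrays left out in turn. Because the detected number moved with the condition, fewer detected probes and a change of the genes cannot be told apart. As a covariate that number left 3 families, with the median change of the 228 going from 0.37 to 0.12. Their median SE went from 0.0953 to 0.0910, and 206 kept their direction. A biological response to the incubation stays open, as untested, and the 10 splits of the 6 samples are too few for a share under 0.05 (228 families in the real one, 1 of 10 as large, and at most 0 in another).

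In the mineral layer 7137 of 49140 probes differed between tag 8 °C and tag −2 °C at day 122 (limma, n = 3 per group), 5600 of them higher. Quantile normalization over all detected values left 178 probes, as an intensity-dependent shift between arrays predicts, so such a shift may account for part of the calls. The calls ended because the median change of the 7137 went from 0.84 to 0.44 and their median SE from 0.213 to 0.305, and that setting itself moved the median family to −0.25. Among the probes detected on all 15 arrays, normalized and tested alone, 1827 passed against 2227, with 1561 shared, which argues against such a shift as the whole cause in that set. Its share of higher calls went from 63.3% to 51.3%, so the shift may account for the excess of higher calls there. With the column names of the second table, which exchange some but not all arrays between days 60 and 122, 8114 probes passed. That argues against this misnaming as the cause of the calls, though not against a misnaming. A full swap of the days was not run. Of the 3674 called probes that were not detected on all 15 arrays 94.3% were higher, against 61.6% of the other 3463, so dim values missing on the arrays with fewer detected probes may account for part of the excess of higher calls. A biological difference between the tags stays open, as untested, and the 10 splits are too few for a share under 0.05 (7137 probes in the real one, 1 of 10 as large, and at most 0 in another).

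For 5 mineral columns of tag 8 °C the 2 deposited tables hold different values under the same name. With the names of the second table the mean variance within groups was 0.966 of that with the names used here. On the same scale the 10 possible splits of the 6 samples ran from 0.850 to 1.00. Among them the 2 namings ranked 6 and 9, counted from the tightest. Taken by the names used here, the values of all 6 mineral columns of tag 8 °C stand in the second table in the order of the sample list, while under its own header 1 of 6 does. A header left in place over re-sorted columns gives that order, which favours the names used here. Values labelled in list order before a re-sorting of the first table give it too. Which naming is right cannot be told apart, because the order leaves both possible and both namings are as loose as other splits of these samples. With the other names the 2 layer differences counted 40 families, 19 of them shared with the names used here, and 104, of which 40 were shared. No biological explanation was tested.

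Over 100 splits of all 30 samples, the layer difference in families (538, at most 256 in another split) and in probes (30296, at most 13995) was reached by 1 split each, the real one, which excludes chance at a share of 0.05. In organic probes, any difference among the conditions was also reached by the real split alone (3843, at most 2755, 1 of 100), a share under 0.05. Another split came near it, and the count was 66 without 1 array, so that share alone does not exclude chance. In organic families 2 of 100 splits were as large (103, at most 115), a share under 0.05 that alone does not exclude chance. In the mineral layer 1 of 100 splits was as large in families (16, at most 9) and in probes (8558, at most 375). For all comparisons of 2 conditions the 10 splits are too few for a share under 0.05. Between the tags at day 122 the real counts were 7 and 4 families in the organic and mineral layers (at most 0 in another split) and 2430 organic probes (at most 1). From day 60 to day 122 they were 148 organic families (at most 0) and 0 mineral ones (20 at an unadjusted p under 0.05 in limma, at most 9 past the threshold in another split). For mineral tag 8 °C at day 60 the count was 2, with 9 in another split, and 2 of 10 splits were as large. With 0 families in limma, all 10 splits are as large: at most 0 in another split for mineral tag 8 °C, organic tag −2 °C and mineral tag −2 °C at day 122 and organic tag 8 °C at day 60 against the control (121, 91, 1 and 76 families at an unadjusted p under 0.05). The same holds, with at most 1 and 3 in another split, for tag −2 °C at day 34 against the organic and mineral controls (62 and 28 unadjusted), and with 0 for day 34 to 122 in the mineral layer (5 unadjusted). From day 34 to day 122 at tag −2 °C in the organic layer the real count was 0 (12 unadjusted), while another split gave 109, which points to a structure of the samples.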

How the results depend on the processing

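The unscaled values, the common signal floor, the covariate for detected probes, the names of the second table and the added layer difference were chosen only after the data were seen. Of 662 recomputed planned values 498 kept their side of the threshold or stayed within 1.5 times, 154 moved and 10 lost their call, and of 48 added ones 18 stayed and 30 moved. For counts of calls only the total was compared, and a count of 0 that stayed 0 is among those kept. Direction was not compared. For organic tag 8 °C at day 122 against the control the total stayed at an equal total, although most calls there were lower instead of higher. The 498 are therefore no measure of how stable the calls are. Leaving out single replicates gave 1368 values of 84 results, each a named family in 1 comparison: 1254 kept direction and call, 114 lost the call and 0 turned. Families named because the values of 2 groups did not overlap cannot turn when 1 replicate is left out. For these the 0 was fixed in advance and is no evidence of stability. Most of the 1368 values came from the 36 families of the layer comparison, where only 1 of 30 arrays was left out at a time. Where nothing else is said, the cause was not tested. Signal over background limits what was seen, since the lowest deposited intensity differed between arrays, and no depth applies to arrays.

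Quantile normalization gave 174 families between the layers, 553 and 1 for any difference among the organic and mineral conditions, 723 for organic tag 8 °C at day 122 against the control and 734 against day 60. It gave 1 and 1 between the tags in the organic and mineral layers, 0 for mineral tag 8 °C at day 60 (20 at an unadjusted p under 0.05 in limma), and 0 for both layer differences (10 and 524 unadjusted). In probes it gave 20876 and 2411 for any difference in the organic and mineral layers and 6 and 178 between the tags, and in organism groups 0 between the layers and 5 for organic tag 8 °C at day 122. By construction it pulls the median family away from 0 where arrays differ in detected probes. The median moved to −0.85 for organic tag 8 °C at day 122, −0.40 and −0.43 for organic tag −2 °C at days 122 and 34, 0.16 and 0.26 for mineral tag −2 °C at days 122 and 34, and −0.11 for mineral tag 8 °C at day 60. In the organic layer it turned pel_Cdeg (−0.13), merT (−0.26), mcra (−0.14), sqr (−0.20), mce3 (−0.060), codh (−0.74), rubisco (−0.69), amyA (−0.70), vana (−0.66), amoa (−0.33), nosz (−0.72) and phytase (−0.47) for tag 8 °C at day 122. Against day 60 it turned pel_Cdeg (−0.0025), merT (−0.23), cmr6 (−0.32), sqr (−0.18), mcra (−0.16), b_lactamase (−0.12), tannase_Cdeg (−0.47) and camdcab (−0.47), and between the tags mtbC_mttC (−0.054), replicase_Carmovirus (−0.0036), cusC (−0.052), groES (−0.046) and rndA (−0.31).

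Without scaling 63 families differed between the layers, 532 among the organic conditions, 722 for organic tag 8 °C at day 122 against the control, 591 against day 60 and 11 between the organic tags. Between the layers glucoamylase (−0.047), nifh (−0.016), nirs (−0.041), nosz (−0.033), urec (−0.062), dsra (−0.070) and dsrB (−0.085) turned. For organic tag 8 °C at day 122 codh (−0.71), rubisco (−0.69), amyA (−0.68), vana (−0.57), amoa (−0.41), nosz (−0.65) and phytase (−0.37) turned, and between the tags groES (−0.019) and rndA (−0.24). At an equal total, and as shares of the signal, the counts were 29 for any mineral difference, 2 for mineral tag 8 °C at day 122, 2 and 14 between the organic and mineral tags, 7 for mineral tag 8 °C at day 60, 354 for organic day 122 against day 60, and 5 and 66 for the planned and added layer differences. As shares 0 organism groups differed between the layers and 1 for organic tag 8 °C at day 122. There codh was −0.048 at an equal total and −0.047 as a share, rubisco −0.027 and −0.026, and amyA −0.015 and −0.013. The layer split was 257 higher and 264 lower at an equal total and 256 and 264 as shares.

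As mean log2 of probes detected on all arrays, 32 and 34 families differed among the organic and mineral conditions, 144 for organic tag 8 °C at day 122 (110 higher and 34 lower), 3 for mineral tag 8 °C at day 122, 82 and 35 between the tags and 7 for mineral tag 8 °C at day 60. The count was 0 for organic day 122 against day 60, 1 for organic day 122 against day 34 at tag −2 °C, and 42 and 17 for the layer differences. Turned were p48_hypoviridae (−0.56), GAPDH_Euglenozoa (0.12), cda (0.081), xylanase (0.064), acetylglucosaminidase (0.00047) and vana (0.037) between the layers, and 5f1_ppn (0.20), strR (0.087) and coat_Nepovirus (0.12) against day 60. With the common floor coat_Nepovirus was 0.12, and 26 families differed between the organic tags. There the splits were 230 higher and 40 lower for organic tag 8 °C at day 122 and 151 and 17 against day 60. With the covariate 24 families differed among the organic conditions, 3 for tag 8 °C at day 122, 15 between the tags and 0 against day 60. It turned pel_Cdeg (−0.32), sqr (−0.19) and zrt1 (0.026) at day 122, and pel_Cdeg (−0.027), sqr (−0.14) and MT2 (0.12) against day 60. Only probes detected on all arrays, a smaller set, gave 18843 between the layers, 2471 and 3778 among the organic and mineral conditions and 2227 between the mineral tags.

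With all 30 arrays in 1 fit the counts were 55 for any mineral difference, 5 for mineral tag 8 °C at day 122, 13 at day 60 and 18 between the organic tags. Families with at least 3 retained probes, a smaller set, gave 7, 1 between the mineral tags, 1 for mineral tag 8 °C at day 60, and 12 for the planned layer difference. Without the intensity trend 25 organic families, 17 between the mineral tags and 1 for mineral tag 8 °C at day 122 passed. Named as in the second table, mineral tag 8 °C gave 4 at day 122 and 1 at day 60, and the layer differences 40 and 104. Without the 3 mineral samples whose titles end in another letter, 0 families passed for any mineral difference, between the mineral tags and for tag 8 °C at day 60 (limma, 99, 101 and 112 unadjusted), 11 and 16 for the layer differences, 4845 probes for any mineral difference and 1904 between the mineral tags, with fewer samples. The share of mineral composition by condition (0.426) was 0.470 without those samples, 0.355 on log values and 0.350 on detected or undetected probes, its call lost each time.

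With the replicate number as a replicate block, 34 of 38 results stayed within 1.5 times, counts of 0 that stayed 0 included. The other 4 were 2 families and 956 probes for any organic difference, 8 families for any mineral difference, and 4 families for mineral tag 8 °C at day 60. The numbers did not pair the samples: over 30 pairs per layer the mean correlation of same-numbered deviations was −0.030 (−0.499 to 0.395) in the organic and −0.022 (−0.445 to 0.331) in the mineral layer, and 4 and 6 of 15 samples were closest to their own number.

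Leaving out each replicate gave 0 to 197 and 2 to 39 families for any organic and mineral difference, 9 to 236 and 0 to 10 for tag 8 °C at day 122 against the organic and mineral controls, 3 to 23 and 0 to 3 between the organic and mineral tags, and 0 to 9 for mineral tag 8 °C at day 60. For tag −2 °C the ranges were 0 to 2 at organic day 122, 0 to 36 and 0 to 1 at organic and mineral day 34, and 0 to 1 between days 34 and 122 in each layer. Organic day 122 against day 60 gave 55 to 153, and the planned and added layer differences 2 to 26 and 2 to 96. Probes ranged from 66 to 12899 and 5652 to 9160 for any organic and mineral difference, and from 266 to 3851 and 1859 to 6535 between the organic and mineral tags. Organism groups between the layers ranged from 0 to 3, the permutation p of organic detected probes from 0.0609 to 0.152 and of the organic Shannon index from 0.0382 to 0.198. The share of composition by condition ranged from 0.619 to 0.665 in the organic and from 0.472 to 0.610 in the mineral layer.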

Other observations

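All tests in this part were chosen after the data were seen: gene categories, subcategories and phyla as the deposited table names them, each with at least 50 probes, summed and tested in limma like the organism groups.

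Of 25 phyla, 12 differed between the layers. Fusobacteria were higher in the organic layer (0.57 ± 0.12, n = 15 per layer), as were Thermotogae (0.22 ± 0.05), Aquificae (0.18 ± 0.04), Gemmatimonadetes (0.18 ± 0.03) and Spirochaetes (0.17 ± 0.03), at 0.02 to 0.41 without scaling. Lower were the green algae of Chlorophyta (−0.14 ± 0.02), Nitrospirae (−0.09 ± 0.02), the fungal phylum Basidiomycota (−0.09 ± 0.02), Verrucomicrobia (−0.08 ± 0.02) and Planctomycetes (−0.05 ± 0.01). Of 80 gene subcategories 30 differed, with nitrogen assimilation (−0.35 ± 0.05), virulence regulation (−0.33 ± 0.04), genes of prokaryotic viruses (−0.21 ± 0.02), assimilatory nitrogen reduction (−0.16 ± 0.02) and iron uptake of pathogens (−0.14 ± 0.02) lower in the organic layer. Higher were anti-pathogen genes (0.17 ± 0.02, 0.02 without scaling), nitrogen fixation (0.13 ± 0.03, but −0.02 without scaling) and plant hormone genes (0.11 ± 0.01, but −0.04 without scaling). After quantile normalization the signs of all these were the same, and 0 of the 117 groups passed in limma, with 5 at an unadjusted p under 0.05. These counts were not recomputed without single arrays.

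In the organic layer, 9 of 12 categories, 52 of 80 subcategories and 16 of 25 phyla differed between tag 8 °C at day 122 and the control (limma, n = 3 per group). Sulfide oxidation (0.63 ± 0.21), phytic acid hydrolysis (0.43 ± 0.11), methane genes (0.37 ± 0.10) and cold shock (0.29 ± 0.10) were higher, but were −0.35, −0.47, −0.57 and −0.52 after quantile normalization and −0.17, −0.37, −0.43 and −0.51 without scaling. The fungal phylum Ascomycota (0.24 ± 0.07) was −0.72 and −0.56 with those settings. None of these sums was recomputed without single probes. Of families with such functions, the sulfide oxidation gene sqr was −0.0029 without the probe that changed most. In the same way phytase was 0.01 and mcra of methanogenesis −0.16. Lower with the default scaling were Fusobacteria (−0.65 ± 0.24), Aquificae (−0.31 ± 0.07), genes of prokaryotic viruses (−0.13 ± 0.05) and virulence genes for adherence (−0.08 ± 0.02). With quantile normalization 116 of the 117 groups passed and the median family was at −0.85 (−0.80 without scaling), so lower values of these 4 with those settings are no separate evidence. Aquificae were also lower at tag 8 °C than at tag −2 °C at day 122 (−0.31 ± 0.07, adjusted p = 0.0274), where the genes for resistance to multiple metals were higher (0.14 ± 0.02, adjusted p = 0.000152) but −0.32 after quantile normalization and −0.24 without scaling. In the mineral layer 0 of the 117 groups differed in limma between tag 8 °C at day 122 and the control, with 4 at an unadjusted p under 0.05.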
